A study of Rattus rattus with 8 samples.

How the data were processed

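Total RNA from the livers of 8 male WH rats was hybridized to Agilent single-colour arrays, 1 array per animal, without pooling. The deposited values are linear spot intensity (Cy3), divided by a factor per array, as their distribution shows: all are positive, right-skewed and neither log-transformed nor centred. Images were read with Agilent Feature Extraction 10.7, per the submitters' processing notes. Background subtraction, feature flags and the scaling step are not given in the sources used here. The median of the deposited values ranged from 0.0888 to 0.101 between arrays and the 75th percentile of named features from 1.08 to 1.09. Groups were taken from the diet dose in the labels, 0 ppm (control, 4 rats) and 2500 ppm (NaPB, 4 rats), both on day 7. The replicate numbers of the groups belong to different animals and do not pair them. The labels give the organism as Rattus rattus. No slide, date or batch is given, so batches were not tested.

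Of 62976 features, 45904 carried 1 gene symbol, 0 carried several and 17072 carried none. Symbols were kept as the probe table gives them. Of the symbols, 11920 were found in the reference gene table, an assembly of Rattus rattus, and 0 feature accessions were, so no coordinates were used. Control spots could not be recognised, so features with a symbol were used for the feature fit, in place of all features that are not control spots, and unnamed features were fitted separately as an addition. Each array was divided by the 75th percentile of its named features. Values under 0.03 were set to 0.03, log2 values were taken, and the features of a gene were averaged. The level of the floor was chosen from the pile-up of low values and the noise between duplicate features, an SD of 0.32 on the log2 scale just above the floor, before any group difference was computed. Across the 11131 genes with exactly 2 features, these correlated at r = 0.972 on an array, against 0.016 for features of different genes. Genes were tested if they lay above the floor on at least 3 arrays of at least 1 group, which left 10944 of 16945 genes. The planned requirement of values on at least 3 arrays of each group was met by every feature, since no values were missing. Of the tested genes, 894 had a value at the floor on some array. Where all 4 control arrays lay at the floor, the fold is given as a lower bound.

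NaPB was compared with control by limma 3.58.1 (lmFit and eBayes, two-sided moderated test) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and a second count at a log2 change of at least 1. Values are means over 4 rats and errors are standard errors of the difference from this fit. 30 gene lists were written, of which 28 had at least 5 measured members and were tested with limma's camera, which ranks a list against all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. The same test was run with the correlation estimated from the data. fry was run as well. Its p tests whether the genes of a list move on balance in one direction, its mixed p whether they change in either direction, and neither compares the list with other genes. Members past the threshold were counted over all genes and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

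Named genes were chosen by rule. They were the 12 largest rises and 12 largest falls among changed genes whose groups do not overlap, at most 3 of them in each direction with a locus or clone identifier as symbol. From each list came up to 4 members past the threshold, the 2 with the largest rise and the 2 with the largest fall, or, if none passed, the member with the largest change. A fixed set was named whether or not it passed: Cyp2b1, Cyp2b2, Cyp3a23/3a1 or Cyp3a1, Cyp3a2, Cyp2c6, Cyp1a1, Cyp1a2, Cyp4a1, Por, Ephx1, Nr1i3, Nr1i2, Cyp2c11, Cyp7a1, Gadd45b, Cdkn1a, Mki67, Ccnb1, Ccnd1, Pcna, Top2a and Mcm2. Cyp2b1, Cyp2c6 and Mki67 are not named in the probe table used here, and Cyp3a1 is named there as Cyp3a23/3a1. This gave 91 genes, of which 19 came from the fixed set. The comparison, test, lists, naming rule and alternative settings, except those said to be added, were fixed before the data were examined.

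Alternative settings were quantile normalization, arrays shifted to the same median, only genes above the median level, a floor at the 20th percentile, the replicate number as a block, array weights, a trended and robust variance prior, a Welch test with separate variances per group, the brightest feature per gene, limma's treat against a log2 change of 0.5, camera with an estimated correlation, and leaving out each array. The Welch test takes the variance of a gene from its own 4 arrays in each group and borrows none from other genes. Scaling to the 75th percentile, also planned as an alternative, is the scaling used. After the data were seen, the deposited scale without further scaling, a floor of 0.1, no filter at the floor and all features were added. The procedure was tested on simulated data of 10944 genes, 200 of them changed. It recovered 47.1% of changes of 0.5 on the log2 scale, 93.9% of changes of 1 and 98.5% of changes of 2, and 10 of its 169 calls were unchanged genes. Without a simulated change 0 genes were called, and of a raised and an unchanged list only the raised list was called. The simulated genes varied independently and had no floor, so lists whose members vary together were not tested in this way. All 35 splits of the 8 arrays into groups of 4 were fitted as well. No samples were left out.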

Results

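Liver gene expression was measured in 8 male rats of the WH strain, with 1 single-colour (Cy3) Agilent array per animal. The rats had eaten diet with sodium phenobarbital (NaPB), a barbiturate that activates the nuclear receptor CAR, at 0 ppm (4 control rats) or 2500 ppm (4 NaPB rats) for 7 days. The number of arrays limits the precision of every value. Each array held 62976 features, of which 45904 carried a single gene symbol, and these covered 16945 genes. Between 31.8% and 34.5% of the named features of an array lay at the floor set for low values, and 10944 genes were measured well enough to be tested. Across the deposited log2 values of all 62976 features, arrays of the control group correlated with each other at r between 0.981 and 0.989. Arrays of the NaPB group correlated at 0.977 to 0.984, and arrays of different groups at 0.973 to 0.984. Genes within an array are not independent replicates.

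The comparison of NaPB with control diet addresses the response of rat liver to the compound, which the series title divides into growth by larger cells and growth by more cells. Several genes of drug metabolism that CAR controls were among the largest rises, and most measured genes of the cell cycle rose as well. Cyp2b2, a cytochrome P450 used as a marker of phenobarbital exposure, rose from a scaled intensity of 5.31 to 128, a log2 change of 4.60 ± 0.13 (here and below SE of the difference, n = 4 rats per group). Glul and Oat, enzymes of the hepatocytes next to the central vein, fell by 1.65 ± 0.18 and 1.80 ± 0.16 on the log2 scale. In all, 1144 of 10944 genes changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 674 higher and 470 lower with NaPB. Of these, 222 changed at least 2-fold, 163 higher and 59 lower. In 1122 of the 1144 changed genes the arrays of one diet all lay above those of the other. Among the changed genes that the naming rule gave, Elovl6 and Pparg were the exceptions. Over all tested genes such separation was seen in 2095, or 19.1%, where chance gives 2.86%. The split between directions depended on the scaling between arrays: 58.9% of the changed genes were higher with the scaling used here, 49.2% after quantile normalization and 41.3% when arrays were brought to the same median. Without control replicate 1 the number of changed genes was 698, and without control replicate 2 it was 625. The number of lower genes was 282 and 240 without these, 294 without control replicate 3, 313 without NaPB replicate 3 and 284 without NaPB replicate 4.

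**Figure D1:**
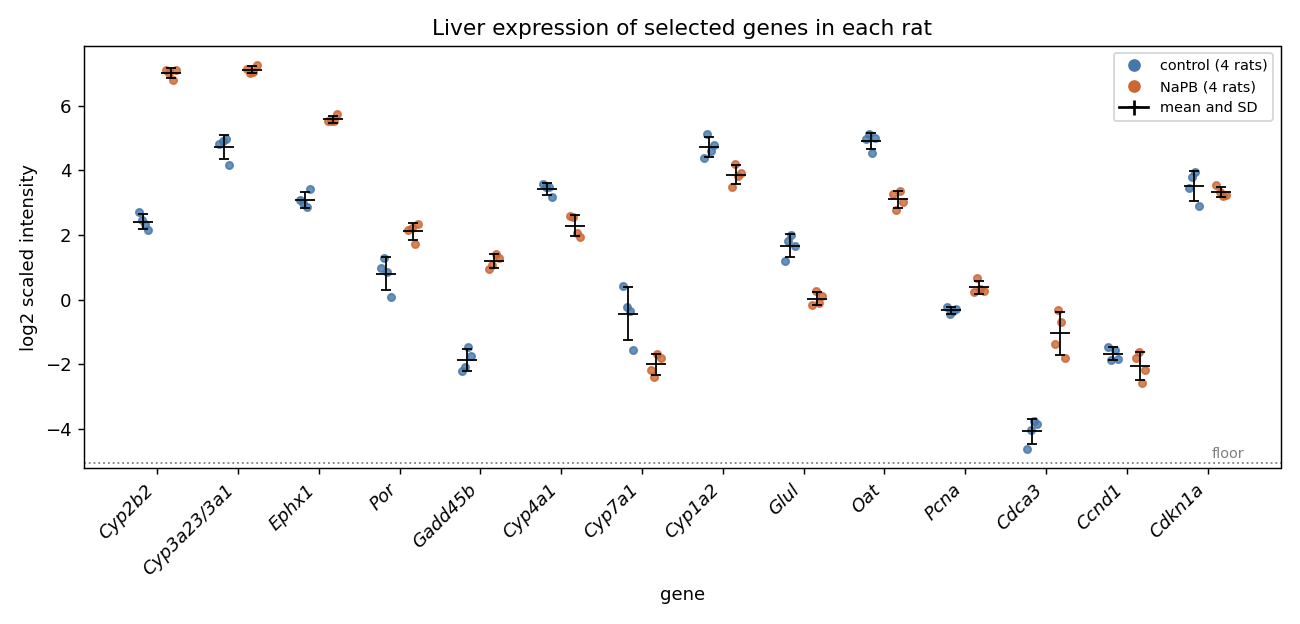
Log2 scaled intensity of 14 genes in each rat, with control and NaPB rats side by side; points are rats, bars the mean and SD of each group (n = 4), and the dotted line is the floor. For Cyp2b2 the 4 NaPB rats lie far above the 4 controls, around a level of 128 against 5.31, while the levels of Glul are 1.02 and 3.18.

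The 12 largest rises were led by Cyp2b21, a P450 of the family that phenobarbital induces, whose log2 change was at least 6.86, since 5 of its 8 control feature values lay at the floor (5.31 with a floor of 0.1). Abcc3, an export pump for conjugated compounds, and Ddit4l, an inhibitor of mTOR signalling, lay at the floor in all 4 control rats and were at least 17.5-fold and 28.5-fold higher with NaPB (log2 changes of 2.40 and 3.10 with a floor of 0.1). Aldh1a1, which makes retinoic acid, rose by 4.34 ± 0.34, the glutathione peroxidase Gpx2 by 4.33 ± 0.28 and the carboxylesterase Ces2c by 3.98 ± 0.18. Gstm3 and Gsta5, which conjugate glutathione, rose by at least 3.97, with 8 of 16 control feature values of Gstm3 at the floor (2.80 with a floor of 0.1), and by 3.83 ± 0.25, and the aldehyde reductase Akr7a3 by 3.35 ± 0.16. Rpesp rose by 3.17 ± 0.28, and Gadd45b, a growth arrest and stress gene, by 3.06 ± 0.18. The adjusted p of these 12 genes was at most 0.00202. The features of Cyp2b2 changed by 3.34 to 5.88 and those of Gsta5 by 0.85 to 5.34, so both means combine unlike values. Cyp2b1 and Cyp2c6 are not named in the probe table used here, and the very similar transcript of Cyp2b1 was not told apart from that of Cyp2b2. Cyp3a1 is named there as Cyp3a23/3a1.

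Among the 12 largest falls were Slc22a8, an importer of organic anions, which fell by 3.09 ± 0.67, and Dhrs7, a short-chain dehydrogenase, which fell by 3.09 ± 0.65. Rdh2, a retinol dehydrogenase with 4 of 16 NaPB feature values at the floor, fell by 2.28 or more (-1.68 with a floor of 0.1). The flavin monooxygenase Fmo1 fell by 2.13 ± 0.32, and the clock gene Per2 fell by 2.10 ± 0.43. Odf3b fell by 2.07 ± 0.33, and the transcriptional regulator Tsc22d1 fell by 1.95 ± 0.25. Apoa4, an apolipoprotein, fell by 1.90 ± 0.28, the peroxisomal oxidase Hao2 fell by 1.88 ± 0.21, the collagen Col27a1 fell by 1.87 ± 0.31 and the lipid transporter Mfsd2a fell by 1.84 ± 0.44. Oat, which breaks down ornithine, completed these 12, whose adjusted p was at most 0.0339. Leaving out 1 array ended the call of Dhrs7 (without control replicate 2, adjusted p = 0.0593), Per2 (without control replicate 1, 0.0525), Slc22a8 (any array other than control replicate 4 and NaPB replicates 1 and 2, up to 0.0666) and Mfsd2a (any array other than control replicate 4 and NaPB replicate 2, up to 0.0800).

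Targets of CAR and PXR, the receptors through which phenobarbital acts, rose together: 21 of 31 measured members rose and none fell, with a median log2 change of 1.31. Adjusted over the list alone, 27 rose and 1 fell. Cyp3a23/3a1, a main drug-oxidizing P450, rose by 2.39 ± 0.17, from a scaled intensity of 26.3 to 138 (adjusted p = 0.000166). Ephx1, the microsomal epoxide hydrolase, rose by 2.49 ± 0.12 (adjusted p = 1.81e-05), and Por, which supplies P450s with electrons, rose by 1.31 ± 0.25 (adjusted p = 0.0138). Cyp3a2, a P450 of adult male rats, did not pass, at 0.21 ± 0.22 (adjusted p = 0.585). Ranked against all other genes by camera, the list was higher with NaPB with the preset correlation (adjusted p = 2e-25) and with an estimated correlation (adjusted p = 0.00158).

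Conjugating enzymes rose with them. Of 34 measured UDP-glucuronosyltransferases, glutathione S-transferases and sulfotransferases, 22 rose and 2 fell (23 and 3 adjusted over the list alone), with a median of 0.65. Outside the CAR and PXR list 15 of 27 rose. Both that fell were sulfotransferases: Sult2a1, which sulfates steroids and bile acids, fell by 1.00 ± 0.23, and Sult1a1, which sulfates phenols, fell by 0.48 ± 0.12. Targets of Nrf2, the regulator of antioxidant defence, rose in 11 of 16 cases and fell in none (16 rose adjusted over the list alone), with a median of 1.46, and 8 of the 12 members outside the CAR and PXR list rose. Genes that supply NADPH and UDP-glucuronate rose in 6 of 11 cases and fell in none (8 rose adjusted over the list alone), with a median of 0.47, among them malic enzyme Me1 at 1.45 ± 0.25 (adjusted p = 0.00906). Outside the CAR and PXR list 4 of 9 rose, and Me1 is also a member of the Nrf2 list. The camera test placed all of these lists above other genes, with adjusted p = 2.19e-11, 1.55e-15 and 3.4e-05 in this order, and adjusted p = 0.00276, 0.00972 and 0.0231 with an estimated correlation. Leaving out 1 array ended the calls of Sult2a1 (without control replicate 1, 3 or 4 or NaPB replicate 3, adjusted p up to 0.0775) and Sult1a1 (any array other than control replicate 4 and NaPB replicate 3, up to 0.0921).

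Of 4 measured targets of the aryl hydrocarbon receptor AhR, too few to test as a list, 2 rose and 1 fell, counts that were the same adjusted over the list alone. The quinone reductase Nqo1 rose by 1.52 ± 0.27 and the glucuronosyltransferase Ugt1a6 by 1.06 ± 0.07, whereas Cyp1a2, a P450 that oxidizes caffeine, fell by 0.87 ± 0.19 (adjusted p = 0.0235). Without control replicate 2 or 4 or NaPB replicate 3 or 4 the call of Cyp1a2 was lost (adjusted p up to 0.0545). Cyp1a1, the most inducible AhR target, lay near the floor, with 28 of 40 control and 9 of 40 NaPB feature values at it, so that its change could not be sized, and it did not pass (adjusted p = 0.238). In heme metabolism 1 of 11 members rose (4 adjusted over the list alone), the biliverdin reductase Blvrb at 0.63 ± 0.09, and the list did not pass (median 0.15, adjusted p = 0.274). Hepatic transporters split, with 6 of 17 higher and 5 lower (7 and 5 adjusted over the list alone): the drug exporter Abcb1b rose by 1.78 ± 0.24 and the exporter Abcg2 fell by 0.62 ± 0.12. Of the 13 transporters outside the CAR and PXR list, 2 rose and 5 fell. With its brightest feature alone Abcb1b was at 0.57 and no longer passed (adjusted p = 0.131). The median of the transporters was negative, at -0.15, while their mean of 0.21 and the direction of the test were positive (adjusted p = 0.663).

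Of 27 constitutive and sex-biased P450s, 12 fell and 3 rose, counts that were the same adjusted over the list alone, with a median of -0.27. The risers included Cyp26a1, which degrades retinoic acid, at 2.44 ± 0.26, and Cyp2c12, the P450 typical of female rats, at 2.04 ± 0.20 (adjusted p = 0.000948 and 0.000768). Cyp17a1, a steroid hydroxylase, fell by 0.90 ± 0.19 and the arachidonic acid oxidizing Cyp2j3 fell by 0.73 ± 0.19. Cyp2c11, the main P450 of male rats, was at -0.27 ± 0.18 and did not pass (adjusted p = 0.361). The list was lower with the preset correlation (adjusted p = 0.00409) but not with the estimate (adjusted p = 0.059 with an estimated correlation). Calls were lost without 1 array for Cyp17a1 (without control replicate 1, adjusted p = 0.0556) and Cyp2j3 (any array other than control replicate 3, up to 0.105).

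Nuclear receptors themselves moved both ways, with 3 of 18 higher and 2 lower (4 and 3 adjusted over the list alone). Ahr rose by 0.90 ± 0.15 and Pparg, a regulator of fat storage, rose by 0.95 ± 0.24. Nr1i3, which encodes CAR, fell by 0.70 ± 0.18 (adjusted p = 0.039), and its partner Rxra fell by 0.57 ± 0.11. Nr1i2, which encodes PXR, was at -0.43 ± 0.13 and did not pass (adjusted p = 0.076). The median of the list was -0.06 while its mean of 0.05 and the direction of the test were positive (adjusted p = 0.946). Without 1 array the calls were lost for Pparg (any array other than control replicate 3 and NaPB replicate 1, adjusted p up to 0.105) and Nr1i3 (any array other than control replicate 4 and NaPB replicate 2, up to 0.0901).

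Genes of the cell cycle and of DNA replication rose in 36 of 42 measured cases and fell in none (39 rose adjusted over the list alone). Their median log2 change was 1.24, with 9 members whose controls were all at the floor taken at their bound, and 0.79 with a floor of 0.1. Spc25, part of the kinetochore, rose by at least 3.05, with 5 of 8 control feature values at the floor (1.37 with a floor of 0.1), and Cdca3, which promotes entry into mitosis, by 3.02 ± 0.33 (adjusted p = 0.000287 and 0.00104). The mitotic cyclin gene Ccnb1 was at least 3.91-fold and the topoisomerase gene Top2a at least 2.74-fold higher, since all 4 controls lay at the floor, as did 3 of 12 NaPB feature values of Top2a, and both calls were lost with a floor of 0.1. Pcna, a clamp of the replication machinery, rose by 0.71 ± 0.11 and the replication helicase gene Mcm2 by 0.72 ± 0.18. Ccnd1, a cyclin of early G1, was at -0.38 ± 0.20 and did not pass (adjusted p = 0.276). The list was higher with the preset correlation (adjusted p = 3e-29), but its members varied together, with an estimated correlation of 0.606, and it did not pass on that basis (adjusted p = 0.142 with an estimated correlation). In limma's fry test, which asks whether the genes of a list move on balance in one direction, it passed (adjusted p = 0.000797). Fry does not compare a list with other genes. The transporter (fry adjusted p = 0.000246), heme (0.00837) and p53 lists (0.0491) also passed in fry, but not in camera. PPAR-alpha targets (fry adjusted p = 0.0723) and clock genes (0.0809) passed in camera with the preset correlation, but not in fry. Markers of lymphocytes, which can also divide, had a median of -0.06. The call of Mcm2 was lost without 1 array (any array other than control replicate 1 and NaPB replicate 3, adjusted p up to 0.0973).

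**Figure D2:**
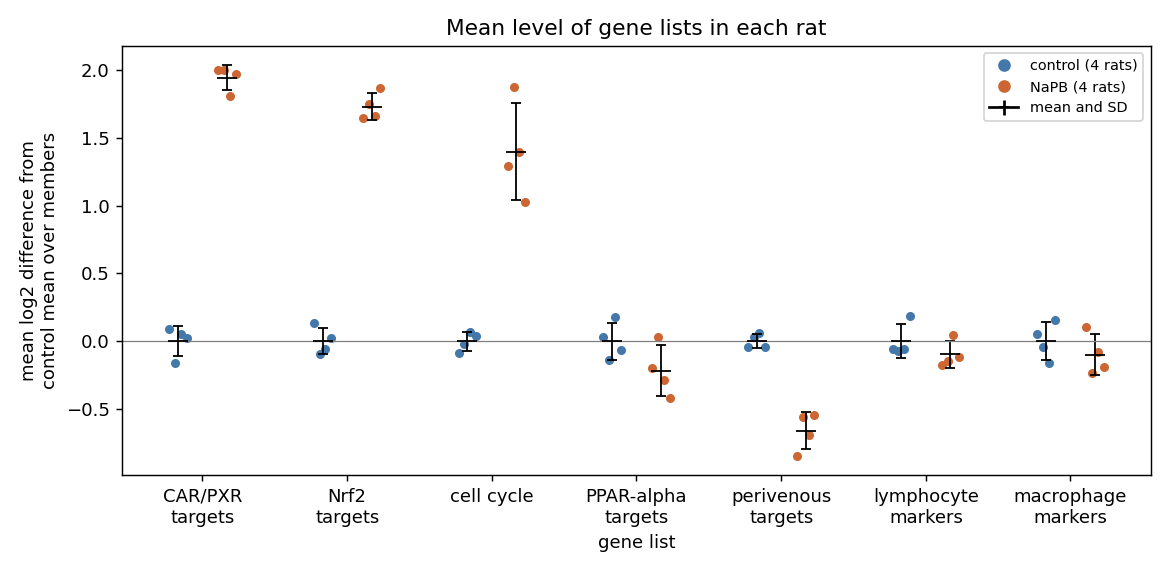
Mean log2 difference from the control mean over the members of 7 gene lists, 1 point per rat, with control and NaPB rats side by side. Cell cycle genes lie higher in the NaPB rats, with a median member change of 1.24, and the perivenous targets lie lower, with a median of -0.65.

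Of 17 p53 and growth arrest genes only Mdm2, the p53 inhibitor, rose, at 0.93 ± 0.08, and none fell (1 rose adjusted over the list alone). Cdkn1a, a p53 target that halts the cell cycle, was at -0.19 ± 0.21 (adjusted p = 0.598), with features between -0.86 and 0.17. This list had a median of -0.0078, a mean of 0.06 and an upward test that did not pass (adjusted p = 0.614). Of 21 genes of the endoplasmic reticulum and integrated stress responses 4 rose and none fell (6 rose adjusted over the list alone), with asparagine synthetase Asns at 1.65 ± 0.31 and the pseudokinase Trib3 2.84-fold higher (adjusted p = 0.0113). That list did not pass (median 0.01, adjusted p = 0.277) except without control replicate 3 (adjusted p = 0.0278). Of 17 immediate early and heat shock genes 2 rose and none fell, the same adjusted over the list alone, namely the transcription factors Atf3 at 1.21 ± 0.26 and Klf6 at 0.61 ± 0.11 (list median -0.07, adjusted p = 0.708). The call of Atf3 was lost without control replicate 1 or NaPB replicate 1, 2 or 4 (adjusted p up to 0.0583). It was also lost with a floor of 0.1 and with the brightest feature of the gene.

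Targets of beta-catenin in the perivenous zone, around the central vein, fell in 6 of 11 measured cases and rose in none, the same adjusted over the list alone, with a median of -0.65. Glul, which makes glutamine from ammonia, fell from a scaled intensity of 3.18 to 1.02 (adjusted p = 0.000993) and Oat from 30 to 8.59 (adjusted p = 0.000451). The list was lower in camera with the preset correlation (adjusted p = 2.74e-05) and with an estimated correlation (adjusted p = 0.0234). Genes of gluconeogenesis and amino acid breakdown fell in 4 of 20 cases and rose in 1 (5 and 1 adjusted over the list alone), with a median of -0.24: the tyrosine aminotransferase Tat fell by 0.67 ± 0.16 and Hpd, a later enzyme of tyrosine breakdown, rose by 0.39 ± 0.08. This list was lower with the preset correlation (adjusted p = 0.00166) and did not pass otherwise (adjusted p = 0.284 with an estimated correlation). The call of Hpd was lost after quantile normalization (adjusted p = 0.0821), with arrays at the same median (0.0596) and without control replicate 1, 3 or 4 or NaPB replicate 1 or 4 (adjusted p up to 0.0598), and that of Tat without any array other than control replicate 4 and NaPB replicate 1 (up to 0.0787).

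In lipid metabolism, targets of PPAR-alpha, the regulator of fatty acid oxidation, fell in 6 of 32 cases and rose in none (7 fell adjusted over the list alone), with a median of -0.21. Cyp4a1, which hydroxylates fatty acids, fell by 1.14 ± 0.17 and Acadm, a dehydrogenase of beta-oxidation, fell by 0.65 ± 0.08 (adjusted p = 0.00423 and 0.00133). The list was lower with the preset correlation (adjusted p = 0.000576) and did not pass otherwise (adjusted p = 0.437 with an estimated correlation). Genes of cholesterol synthesis rose in 5 of 19 cases and fell in none (9 rose and 1 fell adjusted over the list alone), with a median of 0.45, among them Mvd at 0.86 ± 0.20 and Sc4mol at 0.84 ± 0.22. That list was higher with the preset correlation (adjusted p = 0.000191) and did not pass otherwise (adjusted p = 0.427 with an estimated correlation). Lipogenic genes divided, with 3 of 21 higher and 2 lower (3 and 3 adjusted over the list alone): the fatty acid elongase Elovl6 rose by 1.04 ± 0.25, while Elovl5 fell by 0.63 ± 0.10 and the triglyceride-forming Dgat2 fell by 0.46 ± 0.09. Their median of -0.05 and the test pointed down and their mean of 0.01 up (adjusted p = 0.839). Genes of bile acid synthesis fell in 4 of 17 cases (5 fell and 1 rose adjusted over the list alone), with Cyp7a1, the rate-limiting enzyme, at -1.57 ± 0.37 and Cyp7b1 at -0.84 ± 0.18, and the list did not pass (median -0.03, adjusted p = 0.323). Leaving out 1 array ended the calls of Mvd (any array other than control replicate 3 and NaPB replicate 3, adjusted p up to 0.0839), Sc4mol (any array other than NaPB replicate 3, up to 0.105), Elovl6 (any array other than NaPB replicate 1, up to 0.0937), Cyp7a1 (any array other than control replicate 4, up to 0.0856) and Cyp7b1 (without control replicate 2 or NaPB replicate 2, 3 or 4, up to 0.0674).

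Clock genes fell in 2 of 14 cases and rose in 1 (5 and 2 adjusted over the list alone), with a median of -0.27. Per2 was one of those that fell, Tef, a clock-controlled transcription factor, fell by 0.84 ± 0.17, and Per3 rose by 0.34 ± 0.08, with features at 0.23 to 1.22 and 10 of 20 control and 8 of 20 NaPB feature values at the floor, a call lost with a floor of 0.1 (adjusted p = 0.434). The list was lower with the preset correlation (adjusted p = 0.0436) and did not pass otherwise (adjusted p = 0.487 with an estimated correlation). Its call was also lost after quantile normalization (adjusted p = 0.0766), with arrays at the same median (0.0798) and without control replicate 1 (0.0588), control replicate 2 (0.0772) or NaPB replicate 3 (0.1). It was lost as well with the floor at the 20th percentile (0.121), with a floor of 0.1 (0.0524) and with separate variances per group (0.132). Acute phase proteins rose in 2 of 23 cases and fell in 1 (2 and 2 adjusted over the list alone): Lcn2, an iron-trapping defence protein, rose by 2.07 ± 0.39, the plasma protein Orm1 rose by 0.71 ± 0.19 and Itih3, which binds hyaluronan, fell by 0.46 ± 0.08. As a list they did not pass (median -0.12, adjusted p = 0.0515), but were lower without control replicate 1 (adjusted p = 0.0411), control replicate 4 (0.0451) or NaPB replicate 1 (0.000745). Leaving out 1 array ended the calls of Per2 (without control replicate 1, adjusted p = 0.0525), Per3 (any array other than NaPB replicate 3, up to 0.0927) and Orm1 (any array other than NaPB replicate 4, up to 0.103), and the call of Orm1 was also lost after quantile normalization (0.0585) and with arrays at the same median (0.0502).

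Markers of hepatocytes fell in 3 of 14 cases and rose in 1 (4 and 1 adjusted over the list alone), with a median of -0.17: Fetub and Apoc3, both secreted into plasma, fell by 0.59 ± 0.09 and fell by 0.56 ± 0.09, and the transcription factor Hnf4a rose by 0.57 ± 0.10. The list was lower with the preset correlation (adjusted p = 0.00409) and did not pass otherwise (adjusted p = 0.389 with an estimated correlation), nor after quantile normalization (adjusted p = 0.0654). Bile duct markers rose in 1 of 5 cases, the same adjusted over the list alone, namely the adhesion molecule Epcam at 1.60 ± 0.11 (adjusted p = 0.000159). That list, with a median of 0.35, was higher with the preset correlation (adjusted p = 0.0304) and did not pass otherwise (adjusted p = 0.281 with an estimated correlation), nor without control replicate 1 (adjusted p = 0.0653), with the floor at the 20th percentile (0.0884), with the brightest feature per gene (0.0632) or without the filter at the floor (0.0633). None of 6 red blood cell markers passed over all genes, while 4 fell adjusted over the list alone. The list median was -0.53, with Alas2, the heme synthesis enzyme of red cell precursors, at -0.89 ± 0.24 (adjusted p = 0.0521), and the list was lower with the preset correlation (adjusted p = 0.00312) but not otherwise (adjusted p = 0.389 with an estimated correlation).

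Markers of the other cell types did not pass as lists with all arrays. Without control replicate 3 the macrophage list (adjusted p = 0.0378) and the stellate list (0.0381) were lower, as was the macrophage list without NaPB replicate 1 (0.0253). Of 15 Kupffer cell and macrophage markers the scavenger receptor Cd163 fell by 0.57 ± 0.11 (1 adjusted over the list alone, list median -0.10, adjusted p = 0.2). Of 14 stellate cell and matrix markers 3 fell and 1 rose, the same adjusted over the list alone: Pdgfrb, a growth factor receptor, fell by 1.10 ± 0.11, the collagen Col3a1 fell by 0.50 ± 0.13 and Rgs5 rose by 0.81 ± 0.14 (list median -0.17, adjusted p = 0.165). Of 10 endothelial markers the VEGF receptor Kdr fell by 0.41 ± 0.08 (1 adjusted over the list alone, list median -0.02, adjusted p = 0.209). Of 10 lymphocyte markers Cd8a fell by 0.58 ± 0.16, and 0 passed adjusted over the list alone (adjusted p = 0.429 for the list). None of 4 neutrophil markers passed, or adjusted over the list alone, and they were too few to test as a list, with S100a9 at -0.50 ± 0.42. None of 5 pancreas and fat markers passed, or adjusted over the list alone (list median 0.24, adjusted p = 0.467), with Cidea at 0.87 ± 0.41. Calls were lost without 1 array for Col3a1 (any array other than control replicate 3, adjusted p up to 0.117) and Cd8a (any array other than control replicate 2, up to 0.106).

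**Figure D3:**
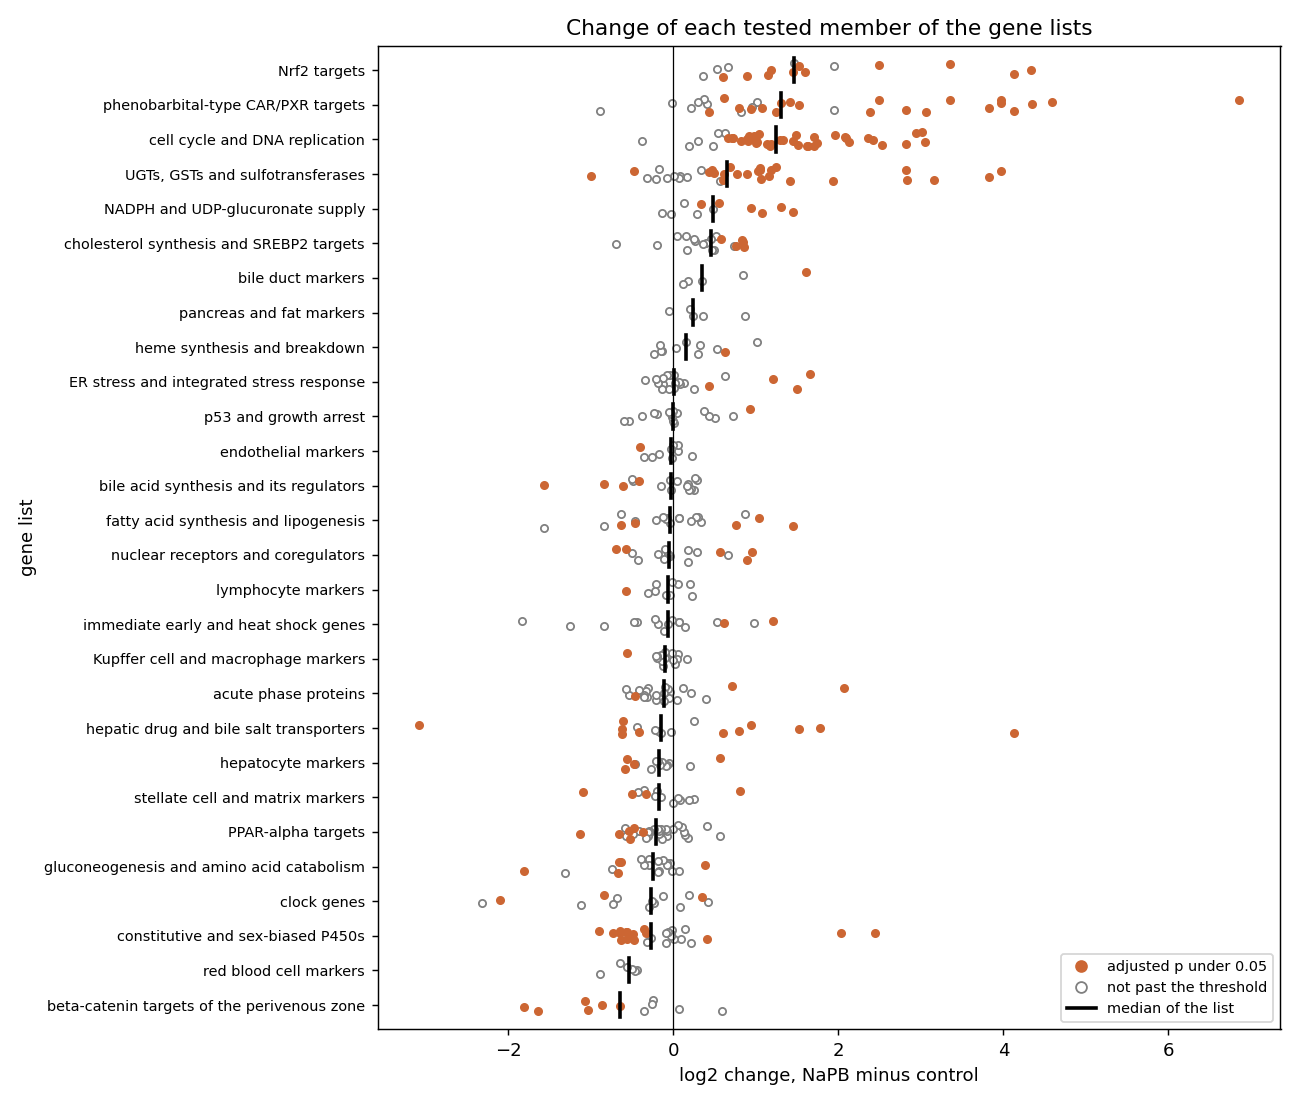
Log2 change with NaPB of every measured member of the 28 gene lists with at least 5 measured members, 1 point per gene, filled where the adjusted p over all genes is under 0.05, with a bar at the list median. The highest medians belong to the targets of Nrf2 (1.46), of CAR and PXR (1.31) and to the cell cycle (1.24), and the lowest to the perivenous targets (-0.65).

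At the level of single features, 2957 of 30504 tested features with a gene symbol changed, 1747 higher and 1210 lower. Without control replicate 1 the number was 1791 and without control replicate 2 it was 1581. Of the 28 gene lists tested, 14 passed with the preset correlation, 7 in each direction, and 5 passed with an estimated correlation. These 5 were the targets of CAR and PXR, the conjugating enzymes, the targets of Nrf2, the NADPH and UDP-glucuronate genes and the perivenous targets. Other splits of the arrays gave a median of 6 lists with the preset correlation, and up to 14, so passing on that basis alone is weak evidence. Some of these splits divide the diets unevenly and keep part of the diet effect.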

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

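The tests of the floor and of immune cells for the cell cycle genes, of a smaller perivenous part, both tests of control replicate 4 and the splits with an estimated correlation were chosen only after the result was seen, as was the naming of Slc1a2, Rhbg and Tbx3. Of the 35 splits of the 8 arrays into groups of 4, only the split by diet (1 of 35) reached 1144 changed genes, and the highest of the others gave 3. For features it was again 1 of 35, with 2957 changed features against at most 5. The other splits mix the diets, so the diet effect widens the spread within their groups and keeps their counts low. With 35 splits no share can be smaller than 1 of 35. Chance is thus argued against for both counts but not excluded. For the 14 gene lists that passed with the preset correlation chance is not argued against. There 2 of 35 splits, the real one included, gave as many, the highest other also giving 14. With an estimated correlation the split by diet gave 5 lists and the other splits 0. In the other splits the diet effect raises the estimated correlation of lists that respond to it. Calls were therefore unlikely there, and this contrast adds little support for the 5 lists.

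Cell cycle and DNA replication genes rose in 36 of 42 cases. The floor under low values is argued against, since 23 of the 27 members whose mean over features lay above the floor on all 8 arrays rose. Single features of these members could still lie at the floor, as 3 of 12 control feature values of Mcm2 did. The floor is therefore not excluded for such members. A single animal is argued against as well, since at least 34 members rose whichever array was left out. More immune cells in the samples could raise the same genes. Lymphocyte markers had a median log2 change of -0.0624 and a mean of -0.0981 ± 0.077 (SE over genes, which does not measure the spread between rats). But levels of different probes cannot be set against each other, so no value shows what rise a small share of dividing immune cells would give these markers. Such cells and dividing liver cells cannot be told apart. The diet with NaPB stays open as the biological explanation, and which cells of the liver carried the transcripts is unknown from whole tissue.

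Perivenous beta-catenin targets fell in 6 of 11 cases. With 1 array left out the number that fell was 4 to 6, and it was 4 without control replicate 1, control replicate 2 or NaPB replicate 3. Scaling between arrays is argued against, since at least 6 members fell under every other scaling tried. A smaller perivenous part in the sampled tissue would lower its genes by about the same factor. The log2 changes of 5 members more restricted to that zone and measured on all arrays had an SD of 1.06, as large in only 1 of the 35 splits (highest other 0.773), with Glul, Oat and the glutamate transporter gene Slc1a2 lower and Rhbg at 0.59 and Tbx3 at 0.07 not passing. The other splits mix the diets, which shrinks any difference between members, and members also expressed outside the zone would fall less. The SD therefore cannot decide whether the perivenous part was smaller. Axin2 was left out of it because 1 NaPB array lay at the floor. It fell by 1.08 or more, with 3 of 8 NaPB feature values at the floor. Its call was lost without control replicate 1 or 3 or NaPB replicate 1 or 3 (adjusted p up to 0.0681). The diet with NaPB stays open as the biological explanation, with no mechanism tested.

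Control replicate 4 lay towards the NaPB rats for genes that fell: for the 70 genes at least 2-fold lower without it, its median displacement was 0.465 on the log2 scale, and 80% of these genes lay that way, while the other controls showed 0.169, 0.0472 and 0.0317 for their own such genes. Tissue or RNA of a treated animal is argued against, since CAR and PXR targets in this array showed a median of 0.0173 of the NaPB change, against 0.301 for the lowered genes. Scaling between arrays is argued against, since the displacement was still at least 0.42 under the other scalings. NaPB replicate 2 lay 0.357 towards the controls for genes that fell, in 87.3% of them. For genes that rose, the displacement of NaPB replicates 1 to 4 towards the controls was 0.212, -0.107, 0.072 and 0.191. Relative to the control mean, pancreas and fat markers averaged 0.944 in control replicate 4 and -0.0795, -0.4 and -0.465 in the other controls. In NaPB rats they averaged 0.0648 to 0.649. Whether the sampled tissue differed was not tested. The design names no difference between control rats, and no biological explanation was tested.

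In 15 of 236 groups of 4 rats, 1 value lay far from the others, as judged by its gap to the nearest value divided by the range of the group. Chance gives about 1 in 20 such groups, or 11.8 here, and 6 of the 15 are NaPB replicate 3. In control rats this ratio was 0.83 for Cyp2b21 and 0.988 for Itih3 (both replicate 1, high), 0.908 for Col27a1 and 0.961 for Cyp1a1 (both replicate 2, high), 0.858 for Me1 (replicate 3, low), 0.907 for Pparg (replicate 3, high) and 0.946 for the mean of the lymphocyte markers (replicate 4, high). Control values of Cyp2b21 and Cyp1a1 lay mostly at or near the floor, which narrows the spread of the other rats, so their ratios can come from the floor. In NaPB replicate 3 it was 0.887 for Aldh1a1, 0.89 for Gsta5 and 0.835 for Col3a1 (high), and 0.886 for Abcc3, 0.953 for Trib3 and 0.945 for Per3 (low, with values of Per3 partly at the floor). In NaPB replicate 4 it was 0.86 for Mdm2 and 0.962 for Ephx1 (both high). Among 7403 tested features without a gene symbol, which the comparisons of genes leave out, 580 changed, 333 higher and 247 lower.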

How the results depend on the processing

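The tests with the deposited scale, a floor of 0.1, no filter at the floor and all features were chosen only after the data were seen. With the replicate number as a block, which pairs unrelated animals, 583 genes changed (354 higher, 229 lower) and 1463 features. The pairing is not borne out, since rats of different groups with the same number correlated across genes, after subtracting group means, at 0.076, 0.061, -0.13 and -0.068, and with other numbers at up to 0.27. With separate variances per group (Welch test) 320 genes changed (219 higher, 101 lower), 87 at least 2-fold, with 930 features and 31 of the 91 named genes. Against a log2 change of 0.5 there were 110 (96 higher, 14 lower), 107 of them at least 2-fold, a stricter question by construction. Arrays shifted to the same median gave 760 lower genes, with the median change of all genes moved to -0.0564, and the floor at the 20th percentile, which tests 13763 genes, gave 303. With 1 array left out, 625 to 980 genes changed, 385 to 556 higher and 240 to 426 lower, and 1581 to 2539 features, with fewer arrays in each fit. An estimated correlation left 5 of 14 lists. PPAR-alpha targets (median -0.208, adjusted p = 0.437) and cell cycle genes (median 1.24, adjusted p = 0.142) were among those lost. Of the 14 lists, 2 were lost with some other scaling and 2 with some array left out, and 0 lists reversed. In some setting 5 further lists passed: transporters with separate variances (adjusted p = 0.00023), acute phase proteins with the block (0.047), the floor at the 20th percentile (0.0458), the trended prior (0.047), the deposited scale (0.0482), no filter (0.0326) or some array left out (0.000745 to 0.0451), and the stress response, macrophage and stellate lists with some array left out (0.0253 to 0.0381). Too few members were left to test the bile duct and the pancreas and fat lists among genes above the median level, with a floor of 0.1 and without some NaPB replicates, and the lymphocyte list with a floor of 0.1. Cyp3a2, not passing in any of these, ranged from -0.004867 (without control replicate 4, reversed) to 0.3689 with 1 array left out, and Cdkn1a, not passing either way, to 0.1683 with its brightest feature. Where no construction is named, the cause was not tested. Of 82 named genes that passed, 77 passed under every scaling (not Hpd, Orm1, Elovl6, Col3a1 and Cd8a), 58 with each array left out and 28 in every setting. The call was lost for 51 with separate variances, 24 with the block, 16 with the floor at the 20th percentile and 11 with the brightest feature. Signal over background limits dim genes: 6001 genes were not tested and 28 higher genes had all 4 controls at the floor.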

Other observations

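The genes named here were chosen after their values were seen, as were the tests. Genes that differ between the sexes in rat liver were looked at without a fixed list or a test of the group. A1bg, more abundant in females, rose by 3.00 ± 0.76 (SE of the log2 difference, n = 4 per group) and the sulfotransferase Sult2a2 by 3.16 ± 0.81, with adjusted p = 0.0398 and 0.0403 from limma and overlapping groups. Both calls were lost without any array other than control replicate 4 and NaPB replicate 2 (adjusted p up to 0.1 and 0.105). Cyp2c13, a P450 of males, fell by 0.64 ± 0.12, the carbonic anhydrase Car3 fell by 1.46 ± 0.19 and the steroid dehydrogenase Hsd3b5 fell by 0.59 ± 0.11 (adjusted p = 0.0141, 0.00239 and 0.0138). Sult2a1, more abundant in females, fell by 1.00 ± 0.23, a call lost without control replicate 1, 3 or 4 or NaPB replicate 3 (adjusted p up to 0.0775). Not passing were Cyp2c7 at -0.02 ± 0.16, Obp3 at -0.15 ± 0.09 and the male P450s Cyp2c11 at -0.27 ± 0.18 and Cyp3a2 at 0.21 ± 0.22 (adjusted p = 0.953, 0.315, 0.361 and 0.585). Cxcl9, a chemokine induced by interferon gamma, rose by 2.82 ± 0.11 (adjusted p = 4.77e-06).

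In 10 genes the 8 rats fell into separate high and low levels that did not follow the diet, with a gap of at least 1.5 on the log2 scale. The gap was 3.91 for Hlf, 3.21 for Mzt1, 2.05 for Tmem79, 1.85 for Gemin6, which has 10 features, 1.76 for Cish and 1.51 for Clca5. Where the floor set the low level the gap is a lower bound: at least 2.52 for Gpm6a, 1.75 for Stc2, 1.64 for Olr471 and 1.61 for Tnfrsf19. Hlf was high in 3 control rats and 1 NaPB rat, and Gemin6 in 3 control rats and 2 NaPB rats.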
